A study of Mus musculus with 4 samples.

How the data were processed

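Polyadenylated RNA of 4 libraries was sequenced, 2 of cells infected with a GFP retrovirus and 2 of cells infected with a retrovirus for FLAG-tagged Fezf2 and GFP. Per the labels' protocols, libraries were made with an Illumina TruSeq kit from 200 ng of total RNA and sequenced as paired ends of 101 bp, from neurosphere cells after at most 1 passage. The series' design text speaks of transfected cells, whereas the treatment protocol describes retroviral infection and also names lentiviral particles. Which of these applies to the libraries is not settled by the labels. The submitters' processing notes name TopHat2, without a version, and the genome build mm9.

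The authors deposited a single gene table, laid out and named as Cuffdiff output. Each group has 1 deposited value per gene, read here as FPKM because Cuffdiff writes that unit in those columns; the header itself gives no unit. The headers number the 2 value columns and name only the contrast. The second was read as Fezf2 and the first as GFP, since the deposited log2 fold change is the second over the first. The names alone would allow the opposite order, and the level of Fezf2 itself checks the reading. Per the file headers, the table also holds the authors' test score, p-value, q-value, a status and a yes or no call. The test score was not used. How the authors pooled the libraries, normalized them or modelled their spread is not given in the sources used here.

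There were 0 columns of values per library. The planned test of library values was therefore replaced by the branch fixed for group values: the authors' own calls at q under 0.05 among the rows marked as tested. All 1054 rows that the table calls significant have such a q. Of 32310 rows, 13535 had been tested, 18775 had not, and 11054 were at 0 in both groups. The smallest deposited p-value is 5e-05, shared by 287 rows. Its q-value in the deposited table is 0.00137, whereas Benjamini-Hochberg adjustment of the tested rows gives 0.00236, so the authors' q-values do not come from this adjustment over these rows alone. Depth per library is unknown, and no counting interval can be given.

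The table shows marks of a spreadsheet. The gene names of 27 rows are dates, of which 2 are called, and 1818 log2 fold changes are stored as Inf and 876 as an error text. Of 18561 rows with both values above 0, the stored log2 fold change of 54 differs by more than 0.001 from the ratio of the values, with the opposite sign in 6 and a call in 0. Folds were therefore computed here from the FPKM values. Rows that share a locus with another row number 11528, of which 265 are called. Their reads are uncertain where the genes overlap, since the sources used here do not state whether strand was used. Called genes named below that share a locus include Pcp4, Fam183b, Lmo3, Gad1, Gria1, Ldb2, Ppp1r1b, Wnt7b, Glul, Lhfpl3, Bmp4, Mif and Chchd10. Sox2, Pax6 and Neurog2, which were not called, also share one. Deposited starts count from 0: 3 mitochondrial starts equal an annotated gene start after adding 1, and 0 do as deposited. Coordinates are therefore given with 1 added, on mm9.

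Differences are Fezf2 minus GFP in log2(FPKM + 1), with a pseudocount of 1 FPKM, which understates the change of low genes. Plain folds of single genes are printed only where both groups reach 1 FPKM. Before the data were examined, 21 gene lists were fixed: glutamatergic transmission, GABAergic identity, corticospinal and subcerebral, callosal and upper-layer, and corticothalamic neuron genes, axon guidance, neural stem and radial glia, intermediate progenitor and proneural, pan-neuronal, astrocyte, oligodendrocyte lineage, microglia and blood cell, vascular and mesenchymal, cell cycle, interferon response, p53 and apoptosis, stress response, Notch pathway, Wnt and BMP pathway, regional transcription factor and reference genes. For each, the called members were counted over all genes, and again after Benjamini-Hochberg adjustment of the authors' p-values over the list alone. The median over members at 1 FPKM or more in either group was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A place outside the central 95% describes these libraries and is no p-value. Lists with fewer than 5 such members were not placed, which left 19 lists.

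Named genes were chosen by a rule fixed with the lists. It took Fezf2, and the 10 largest rises and 10 largest falls among called genes at 1 FPKM or more. The rises and falls passed over identifiers and small RNAs, which were recognized by name alone. The rule also took 20 genes named in advance, and up to 4 called members of each list with the largest difference. Other members named where a count is small were chosen after their values were seen, as were 5 further lists. Some genes that the rule names are not reported here.

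GC content and length are those of the longest GENCODE M21 transcript of each gene symbol, used only as gene properties. Among rows at 1 FPKM or more, 91.8% had a value, as did every such member of the fixed lists. The trend was a quadratic in GC and in log length, fitted by least squares over 12222 genes.

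The list placement was tested on simulated data for this comparison, with 13322 genes. Of 200 unchanged lists of 20 genes, 5% fell outside the central range, and of lists shifted by 0.8 on the log2 scale, 96% fell in the low tail. Simulated genes varied independently, so the 5% checks the code and does not cover lists whose members vary together. Shifts smaller than 0.8 were not simulated. In the same simulation, the fitted trend correlated with the planted one at 0.998. The fit holds the terms of the planted trend, so this too checks the code alone. Alternatives were a smaller pseudocount, none, other FPKM minima, unmatched random lists, centring on the median of all genes, other q thresholds and adjustments, and, chosen after seeing the data, removal of the trend and of rows that share a locus. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.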

Results

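Gene expression was measured by RNA sequencing in neural stem cells from the cortex of C57BL/6 mouse embryos at stage E14.5. The cells had been grown as neurospheres, which are floating clusters of dividing neural progenitors, and were then plated as a monolayer. Growth factor at 20 ng/ml is given for all 4 libraries. They were infected with a retrovirus that carried either GFP alone or GFP together with FLAG-tagged Fezf2, a zinc finger transcription factor needed for the specification of corticospinal and other subcerebral projection neurons. RNA was collected 48 h after infection. The series has 4 libraries, 2 in the GFP group and 2 in the Fezf2 group. The comparison asks which genes respond when Fezf2 is expressed in cortical progenitors. The values analysed were read as FPKM (fragments per kilobase of transcript, scaled for library size). How the libraries were scaled is not given in the sources used here. Each group has 1 value, so no value below has a replicate error of its own. The depth of the libraries is unknown, because the table holds no read counts. Calls of single genes are those of the authors' deposited table at q under 0.05, and the folds between groups were computed here from the FPKM values.

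Fezf2 had 0.423 FPKM in the GFP group and 3142 FPKM in the Fezf2 group. This is a difference of 11.1 on the log2(FPKM + 1) scale, and the q of the authors' deposited table was 0.00137. The gene lies on chromosome 14 from 13174406 to 13178379 (mm9). The value covers both the resident gene and any vector transcript that holds its coding sequence. The value columns carry numbers, not group names; the second was read as Fezf2, and this gene's level checks that reading.

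Of 32310 rows, 13535 had been tested. The authors' deposited table called 1054 of these, of which 619 rose and 435 fell with Fezf2. Over called genes above 0 in both groups, the median fold was 4.08 among those that rose and 2.80 among those that fell. Genes under 1 FPKM in 1 of the groups are included in these medians. A level of at least 4 times that of the other group was reached by 333 of the rising genes, including 37 listed at 0 in the GFP group, and by 74 of the falling genes, including 1 listed at 0 in the Fezf2 group. At the stricter q of 0.01 in the authors' deposited table, 322 genes rose and 163 fell.

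**Figure D1:**
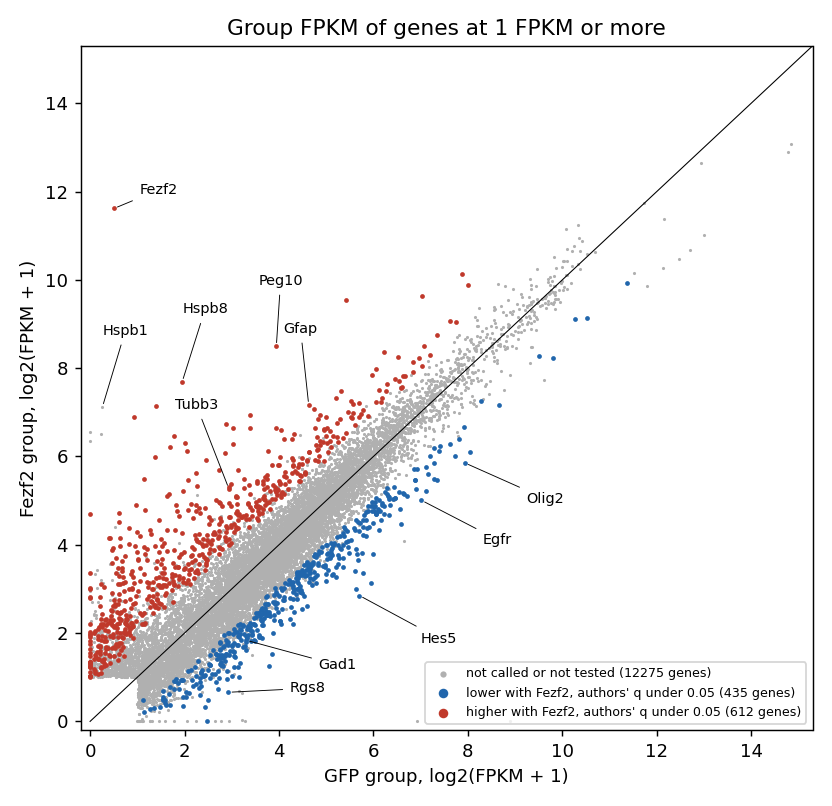
Each point is a gene at 1 FPKM or more in either group, with the log2(FPKM + 1) of the GFP group on the x axis and that of the Fezf2 group on the y axis. The 612 rising genes (red) lie above the diagonal and the 435 falling genes (blue) below it, Fezf2 lies farthest above, and Hspb1 is far from the diagonal without a call.

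After Fezf2 itself, the largest rise on the log2(FPKM + 1) scale among the called genes with a name was that of Pcp4, which encodes a calmodulin-binding protein, from 0.900 to 117 FPKM. With a pseudocount of 0.1 FPKM, Fam183b ranked above Pcp4. Hspb8, a small heat shock protein, rose 71.7-fold, from 2.86 to 205 FPKM. Gstt3, a glutathione transferase, rose 39.5-fold to 62.8 FPKM, and Vgf, a secreted neuropeptide precursor, rose 36.8-fold to 44.02 FPKM. Nupr1, a stress-induced nuclear protein, rose 35.5-fold to 86.7 FPKM. Plau, the urokinase-type plasminogen activator, rose 32.7-fold to 73.3 FPKM. Gadd45b rose 25.5-fold, and Peg10, an imprinted gene derived from a retrotransposon, rose 25.03-fold from 14.4 to 360 FPKM. Fam183b was listed at 0 in the GFP group and had 24.8 FPKM in the Fezf2 group. Pcp4 shares its deposited locus with Igsf5 and Itgb2l, and Fam183b with Olfr314. The q of Pcp4 in the authors' deposited table was 0.0295, against 0.00137 for the other 9.

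On the same scale, the largest fall among the called genes with a name was that of Hes5, a transcriptional repressor induced by Notch, from 51.1 to 6.21 FPKM (8.23-fold lower); with a pseudocount of 0.1 FPKM, Rmrp, Rgs8 and Lmo3 fell further. Gas1, a co-receptor for hedgehog ligands, was 7.80-fold lower, at 61.1 and 7.84 FPKM. Lrrn1 was 7.05-fold lower and Lmo3, a LIM-only cofactor, 9.30-fold lower. Lrrc8b was 7.22-fold lower, Prr18 5.78-fold, the potassium channel gene Kcna2 4.98-fold and Nwd1 4.94-fold. Rgs8 fell from 6.62 to 0.580 FPKM. Rmrp, the RNA of an RNA-processing complex, fell from 4.59 FPKM and was listed at 0 in the Fezf2 group. Its transcript is 281 nt long, and it was kept because small RNAs were passed over by name alone. The choice of these genes passed over 32 rising and 29 falling rows that carry only clone, locus or predicted-gene identifiers, dates or small RNA names.

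The called genes of dividing cells and progenitors mostly fell. All 28 cell cycle genes had a lower FPKM in the Fezf2 group, and 11 of them fell while 0 rose (15 fell when adjusted over the list alone). Their median difference was -1.03 on the log2(FPKM + 1) scale, below all 10000 random lists of genes matched on expression (percentile 0). Mki67, a marker of proliferating cells, fell 3.27-fold from 32.1 to 9.81 FPKM. Cenpe and Cenpf, which act at the kinetochore, fell 3.75-fold and 3.30-fold, and Bub1, a kinase of the spindle checkpoint, fell 3.30-fold. Of 25 tested neural stem and radial glia genes, 6 fell and 2 rose (7 and 2 when adjusted over the list alone), with a median of -0.78 (percentile 0). Egfr, the receptor for epidermal growth factor, fell 4.13-fold from 129 to 31.2 FPKM, Hopx fell 3.59-fold and Hes1 fell 3.40-fold. Sox9 and Msi1 were the 2 that rose. Sox2 was at 134 and 75.9 FPKM and Pax6 at 16.4 and 8.31 FPKM, neither of them called.

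Of 16 tested Notch pathway genes, 5 fell and 0 rose (6 and 0 when adjusted over the list alone). These were Hes5, Hes1, the ligand genes Dll1 (3.43-fold) and Dll3 (3.56-fold), and Notch1, all of which are also members of the stem cell or proneural lists. The median of the Notch list was -0.27, within the central 95% of random lists (percentile 5.31), and -0.57 (percentile 0.02) once a GC and length trend across all genes was taken out. Of 13 intermediate progenitor and proneural genes, 3 fell and 0 rose (4 and 1 when adjusted over the list alone), with a median of -0.59 (percentile 0.25). The third of these, Gadd45g, fell 2.21-fold, but with q recomputed over the tested genes it had 0.0573. Neurog2, a proneural factor, was at 1.26 and 3.00 FPKM, and Eomes, a marker of intermediate progenitors, at 0.0686 and 2.94 FPKM, without a call. Of 13 oligodendrocyte lineage genes, 4 fell and 0 rose (5 fell and 3 rose when adjusted over the list alone), with a median of -0.61 (percentile 0.06), which turned to 0.039 with members under 1 FPKM included (percentile 68.6) and was -1.14 over the 7 at 5 FPKM or more (percentile 0). Olig2 fell 4.31-fold from 245 to 56.8 FPKM, Sox8 fell 3.14-fold, Olig1 fell 3.02-fold and Lhfpl3 fell 2.35-fold. The first 3 encode transcription factors of oligodendrocyte precursors.

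The called pan-neuronal genes mostly rose. Of 19 tested, 6 rose and 1 fell (7 and 1 when adjusted over the list alone), with a median of 0.75 (percentile 99.99). With q recomputed over the tested genes, 4 rose and 1 fell. Tubb3, the neuronal beta-tubulin, rose 5.65-fold from 6.66 to 37.6 FPKM. Chgb, a granin of dense-core vesicles, rose 15.9-fold, Syp, a synaptic vesicle protein, rose 4.11-fold, and Stmn3 rose 3.14-fold. The gene that fell was Elavl4, at 6.73 and 1.84 FPKM.

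Genes of glutamatergic transmission went both ways. Slc17a7, which loads glutamate into synaptic vesicles, rose from 0.222 to 7.23 FPKM, and Dlg4, a scaffold protein of excitatory synapses, rose 2.87-fold to 94.1 FPKM. The AMPA receptor genes Gria1 and Gria2 fell 3.27-fold and 2.93-fold, and 5 of the 14 tested genes fell in all against 2 that rose, both over all genes and when adjusted over the list alone; with q recomputed over the tested genes, 4 fell and 2 rose. The list's median of -0.42 lay below the central range (percentile 1.44), but not without the GC and length trend (median -0.32, percentile 3.84), nor with members under 1 FPKM included (median -0.23); over the 10 members at 5 FPKM or more it was -0.91 (percentile 0.01). Slc17a6 was listed at 0 in both groups.

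Of 9 tested genes on the GABAergic list, 3 fell and 2 rose (5 and 3 when adjusted over the list alone). Gad1, which makes GABA, fell 3.46-fold from 8.91 to 2.57 FPKM. Calb2, a calcium-binding protein of some interneurons, rose from 0.765 to 15.1 FPKM, and Npy, the second that rose, was listed at 0 in the GFP group and had 0.940 FPKM with Fezf2. The median over the 8 members at 1 FPKM or more was -0.81 (percentile 0.16). Over the 20 members above 0 it was -0.035, inside the range of random lists (percentile 19.4), and over the 5 at 5 FPKM or more it was -1.47 (percentile 0.01). Gad2, Dlx1 and Dlx2 lay under 1 FPKM in both groups and had not been tested, and Slc32a1 was listed at 0 in both. Gad1 shares its deposited locus with 2 other rows, so reads that overlap them are uncertain.

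Among genes of projection neuron subtypes, 4 of 21 tested corticospinal and subcerebral genes rose and 1 fell (7 and 2 when adjusted over the list alone). The rising genes were Pcp4, Ldb2 (0.245 to 3.21 FPKM), S100a10 (4.48-fold, to 329 FPKM) and Grb14 (6.66-fold). Nfib was the gene that fell. Crym, a marker of corticospinal and corticothalamic neurons, was at 0.175 and 89.9 FPKM, yet its q in the authors' deposited table was 0.118. Ephb1, an ephrin receptor gene, was at 6.16 and 13.1 FPKM with a q of 0.0553 in the authors' deposited table. Bcl11b was under 1 FPKM in both groups and untested. The list's median was 0.15 (percentile 93.4), 0.28 (percentile 99.6) without the GC and length trend, and 0.046 (percentile 69.7) over the 15 members at 5 FPKM or more.

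Of 7 tested corticothalamic genes, Wnt7b (2.87-fold, to 146 FPKM) and Ppp1r1b (0.484 to 3.65 FPKM) rose and 0 fell (3 and 0 when adjusted over the list alone). The median was 0.75 (percentile 99.4), and 0.40 (percentile 97.0) without the trend, which is inside the central range, as is the 0.088 with members under 1 FPKM included. Tbr1 was under 1 FPKM in both groups. Of 15 tested callosal and upper-layer genes, Rorb (2.91-fold) and Lmo4 (2.39-fold) fell and Cited2 rose 3.26-fold, the same counts as when adjusted over the list alone. The list's median of -0.19 lay within the range of random lists (percentile 19.3). Of 35 tested axon guidance genes, 6 rose and 3 fell (8 and 3 when adjusted over the list alone, and 5 and 2 with q recomputed over the tested genes). The ephrin ligand gene Efnb2 rose 2.56-fold and Efnb3 rose from 0.936 to 5.37 FPKM, while the receptor gene Ephb3 fell 3.30-fold and the netrin gene Ntn1 fell 2.501-fold. The list's median was -0.05 (percentile 53.6).

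**Figure D2:**
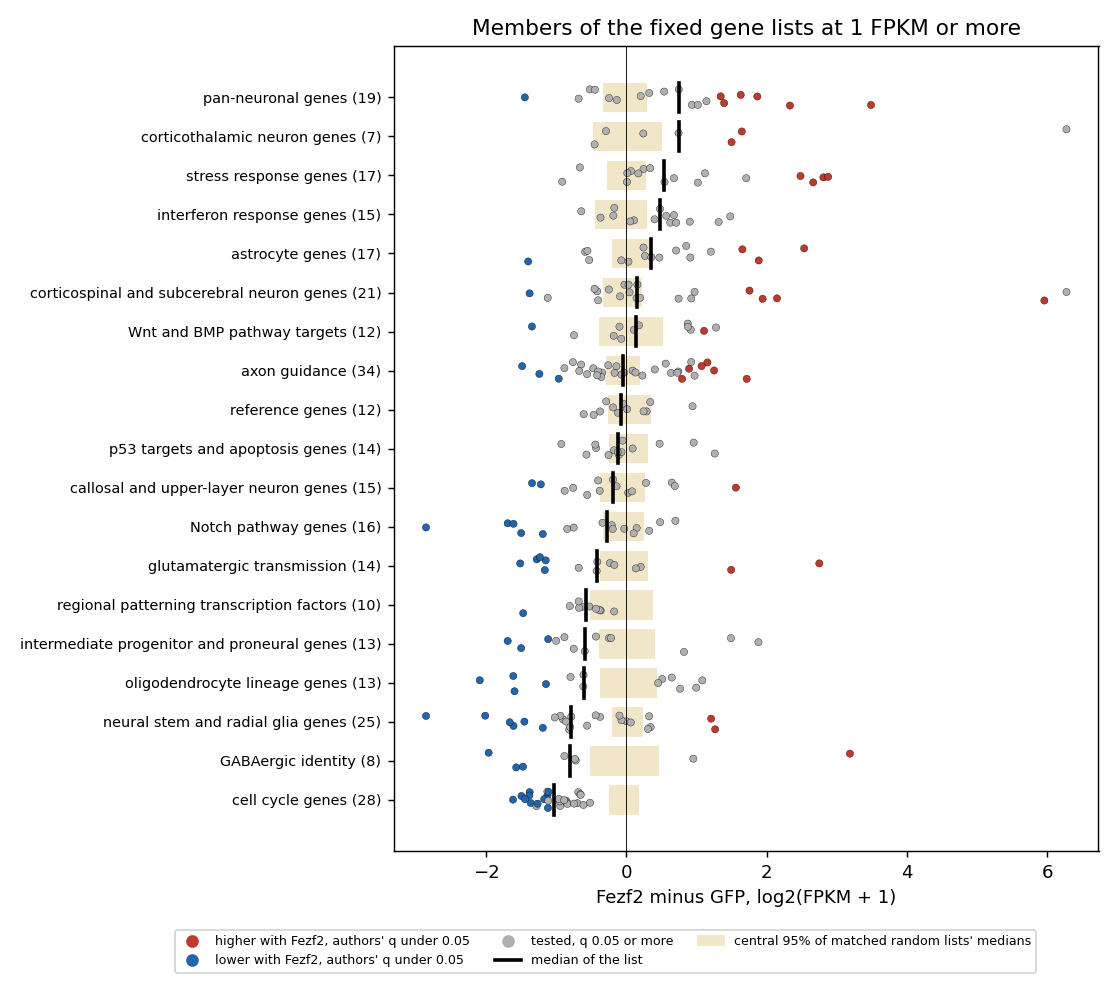
Each point is a list member at 1 FPKM or more in either group, placed by its Fezf2 minus GFP difference in log2(FPKM + 1), and coloured by its call; the number of members is in brackets. The median (black line) of the cell cycle list, -1.03, and that of the pan-neuronal list, 0.75, lie outside the central 95% of the medians of matched random lists (shaded).

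Of 17 astrocyte genes, 3 rose and 1 fell, also when adjusted over the list alone, with a median of 0.36 (percentile 98.5). Gfap, an intermediate filament of astrocytes and adult neural stem cells, rose 6.00-fold from 23.8 to 143 FPKM. Glul, glutamine synthetase, rose 3.71-fold to 943 FPKM, Clu rose 3.22-fold, and Slc4a4, a bicarbonate transporter, fell 2.69-fold. Of 17 tested stress response genes, 4 rose and 0 fell, also when adjusted over the list alone, with a median of 0.55 (percentile 99.95), or 0.32 without the GC and length trend (percentile 99.6). Atf3, a stress-induced transcription factor, rose 12.1-fold to 14.4 FPKM, Trib3 rose from 0.504 to 10.05 FPKM, and Hspa1b rose 11.6-fold to 11.7 FPKM. Hspa1a rose from 0.818 to 9.17 FPKM, and since it is nearly identical to Hspa1b, the split of reads between both is uncertain.

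No interferon response gene of 15 and no p53 target or apoptosis gene of 14 was called, over all genes or when adjusted over the list alone (0 of each). The interferon median was 0.48 (percentile 99.6) and the p53 median -0.11 (percentile 13.6). Cdkn1a was at 400 and 961 FPKM without a call. Of 13 tested Wnt and BMP pathway genes, Axin2 fell 2.89-fold and Bmp4, listed at 0 in the GFP group, rose to 1.16 FPKM (2 rose and 1 fell when adjusted over the list alone), with a median of 0.14 (percentile 66.2) that turned to -0.097 at 5 FPKM or more and to -0.026 without the trend. Of 11 regional transcription factors, Zic1 fell 3.32-fold and was the single call by either adjustment. The median of this list was -0.58 (percentile 1.01), and -0.38 over the 17 members above 0 (percentile 0.07). The 12 reference genes held 0 calls by either adjustment and had a median of -0.08 (percentile 17.3); these 12 include a row named Gapdh on chromosome 1, which is not where the annotation places that gene.

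Markers of other cell types were scarce. Of the microglia and blood cell list 1 member, Cd68, had been tested, at 2.62 and 2.31 FPKM. Of the vascular and mesenchymal list 4 had been tested. Col1a1 rose from 0.133 to 3.37 FPKM and Kdr from 0.0674 to 1.15 FPKM, but with q recomputed over the tested genes Kdr had 0.0603. Both remain called when adjusted over the list alone, where 1 more gene, Acta2 at 13.6 and 6.32 FPKM, also passes, lower with Fezf2.

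Across 12215 tested genes, the difference between groups followed GC content. Spearman's rho with transcript GC was 0.35 and that with transcript length -0.22; these are correlations across genes, which are not independent replicates. The decile of genes with the lowest GC had a median difference of -0.36, with 18 rising and 58 falling genes. The decile with the highest GC had a median of 0.31, with 114 rising and 29 falling genes. The cell cycle, stem cell, oligodendrocyte, GABAergic, proneural, pan-neuronal, astrocyte, interferon, stress and regional lists stayed outside the range of random lists without the trend.

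**Figure D3:**
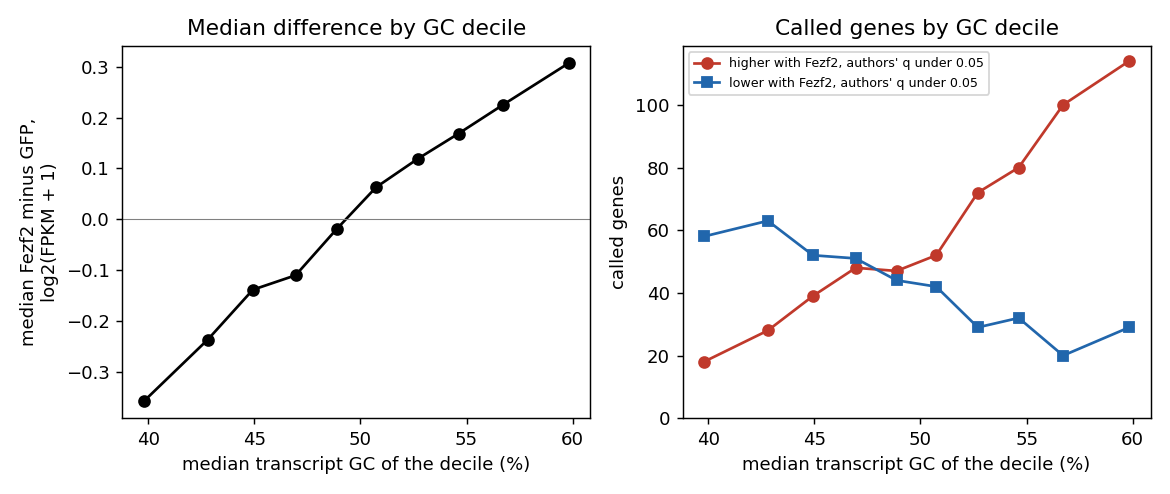
The left panel plots the median Fezf2 minus GFP difference in log2(FPKM + 1) for deciles of genes ordered by transcript GC, and the right panel the number of called genes in each decile. The median runs from -0.36 to 0.31, rising genes go from 18 to 114, and falling genes go from 58 to 29.

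The labels do not say whether the 2 libraries of a group came from separate cultures, so the authors' q may measure technical spread alone. With Benjamini-Hochberg q recomputed from the p-values of the authors' deposited table over its tested genes, 505 genes rose and 337 fell.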

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

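Signals appeared in rows that the authors left untested, so that no call covers them; they enter the report only among all genes at 1 FPKM or more. The small nucleolar RNA genes Snora64 and Snora65 had 93.4 and 81.1 FPKM in the Fezf2 group, and the transcript AK216578 had 6.76 FPKM. All 3 were listed at 0 in the GFP group. They are among 19 untested rows at 1 FPKM or more in either group, and the highest GFP value of an untested row was 6.70 FPKM, close to that of AK216578 with Fezf2. FPKM of short transcripts can rest on few fragments. The fragment counts behind these values are unknown, and no explanation was tested for these rows.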

How the results depend on the processing

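No paired analysis was possible because the table holds 1 value per group and no values per library. For the same reason the variants chosen in advance that leave out a library, block on the replicate number, rescale between libraries, refit with limma, edgeR or DESeq2, or run camera were not run, and depth limits cannot be stated. The counts of 619 rising and 435 falling genes moved by more than 1.5 times under a q of 0.01 alone, to 322 and 163. Under the other thresholds and adjustments chosen in advance they lay between 502 and 616 and between 340 and 435. With q recomputed over all tested genes and without rows that share a locus, both chosen after seeing the data, they lay between 489 and 505 and between 300 and 337. The log2 difference of Fezf2 was 11.1 with a pseudocount of 1, 12.55 with 0.1 and 12.86 with none. Of the 19 placed lists, 12 lay outside the random range, and between 8 and 12 did under the alternatives. When members under 1 FPKM were included, the oligodendrocyte median turned to 0.039. The medians of the glutamatergic list (-0.23), the GABAergic list (-0.035) and the corticothalamic list (0.088) moved inside the random range. This alternative adds members near 0, whose differences are small by construction. The oligodendrocyte list was already split without them, with 6 of 13 members higher with Fezf2 and 7 lower. When the GC and length trend was removed, the glutamatergic (-0.32) and corticothalamic (0.40) medians moved inside the range, while the corticospinal (0.28) and Notch (-0.57) medians moved outside it; the cause was not tested further. Among lists inside the range, the callosal (0.028) and axon guidance (0.063) medians changed sign with members under 1 FPKM, axon guidance (0.12) and Wnt and BMP (-0.026) without the trend, and Wnt and BMP (-0.097) and imprinted genes (-0.23) over members at 5 FPKM or more, all staying inside. Without a pseudocount the GABAergic (-1.36) and pan-neuronal (1.24) medians were larger, and with 0.1 they were -1.27 and 1.20. Over members at 5 FPKM or more the proneural median was -0.997, and with those under 1 FPKM it was -0.25, both outside the range. Centring moved every gene alike by the median log2 ratio of -0.03, and a pseudocount cannot turn the direction of a single gene, so neither tests the directions of the named genes.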

Other observations

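Another 5 gene lists were written after the values had been seen, so neither their calls nor their places among random lists are independent evidence. Of 21 tested glutathione and antioxidant enzymes, 8 rose and 0 fell (6 and 0 with q recomputed over the tested genes), with a median of 0.64 (percentile 100 of matched random lists). Gstm1, a glutathione transferase, rose 4.76-fold from 235 to 1117 FPKM, Nqo1, a quinone reductase, rose 13.1-fold and Srxn1, sulfiredoxin, rose 4.12-fold. Hmox1, another gene of the antioxidant response, was at 50.2 and 50.7 FPKM. Of 5 tested small heat shock protein genes, Hspb8 and Cryab (3.86-fold) rose, and 3 (Hspb1, Hspb2 and Hspb6) were not called. All 5 were higher in the Fezf2 group, with a median of 2.86 (percentile 100). This is the value of Hspb2, at 0.216 and 7.83 FPKM. Hspb1 and Hspb2 reached 1 FPKM only in the Fezf2 group. The median was 1.59 over the 8 members above 0. It was 4.65 with a pseudocount of 0.1 and 5.18 with none. Of 8 dense-core vesicle genes, Vgf, Chgb and Scg2 rose and all 8 were higher, with a median of 1.08 (percentile 99.97).

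Hedgehog pathway genes went both ways. The ligand gene Shh rose 10.2-fold from 1.25 to 12.8 FPKM and the co-receptor gene Boc rose 3.63-fold, while the co-receptor genes Gas1 and Cdon fell 7.80-fold and 5.31-fold. The receptor gene Ptch1, itself a target of the pathway, was at 54.2 and 35.9 FPKM without a call, and the list's median was -0.17 (percentile 28.2). Of 22 tested imprinted genes, Cdkn1c, which encodes an inhibitor of cyclin-dependent kinases, rose 21.5-fold from 1.24 to 26.6 FPKM, Peg10 rose 25.03-fold and Peg3 rose 2.94-fold. Rasgrf1 also rose, a call lost with q recomputed over the tested genes, Peg12 fell 4.42-fold, and the list's median of 0.20 lay within the range of random lists (percentile 94.6), as did the -0.23 over members at 5 FPKM or more (percentile 8.19). Some large differences were not called. Of 210 tested genes that differed by at least 2 on the log2(FPKM + 1) scale, 39 had no call, of which 29 were higher in the Fezf2 group. Hspb1 was at 0.198 and 138 FPKM with a q of 0.184 in the authors' deposited table, and the neighbours Crym and Tmem159 are also among them, the latter at 0.108 and 9.80 FPKM.

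In the patterns weighed next, the tests of the GC trend in genes far from a call, of mitochondrial RNA, and of paralogs and copy number were chosen only after the result was seen. GC-rich and short genes were higher with Fezf2, and AT-rich and long genes lower. The trend is not limited to called genes: Spearman's rho across the 8132 genes with a q of 0.5 or more in the authors' deposited table was 0.30, as a GC-dependent bias between the libraries would give. Such a bias is therefore a candidate source of part of the differences, and a broad biological shift with Fezf2 stays open as well, since both follow the groups. After removal of the trend, the cell cycle and the neural stem medians still lay at percentile 0 and the pan-neuronal median at percentile 100 of matched random lists. The median GC of these lists was 47.2%, 50.7% and 49.7%. GC deciles 4 to 6, with a median GC from 46.9% to 50.7%, had median differences from -0.11 to 0.063. The GC part of the trend was thus small at their GC, and its removal had little to change. Length was not compared in this way, and the longest decile of genes had a median of -0.26, against 0.18 for the shortest. With GC and length both taken out, the list medians were -1.04, -0.75 and 0.73 in the same order. This argues against the trend as the whole source for these lists alone. The glutamatergic and corticothalamic medians did move inside the range, so part of those may come from the trend.

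All 11 mitochondrial rows were lower with Fezf2, with a median of -1.87, although 1 of them was called. Their share of the summed FPKM was 16.9% in the GFP group and 5.09% in the Fezf2 group. The 1061 nuclear genes in the GC range of mitochondrial transcripts had a smaller median fall, of -0.36. Of 10000 random lists of such genes, 0 had a median as low as the mitochondrial one, the lowest being -0.91. Mitochondrial rows may vary together, and some share a locus, whereas the genes of random lists were drawn singly. The lists therefore weigh against the GC trend as the whole source less than 11 separate genes would. A general fall of the respiratory chain is argued against by 82 nuclear genes of it, whose median was 0.31, with 77 of them higher in the Fezf2 group. By call, 2 of them rose and 0 fell, and the GC and length trend was not taken out of this median. These values therefore do not establish a rise. A change of mitochondrial RNA itself and a difference between groups in RNA handling or in selection of polyadenylated RNA stay open and may both apply; neither was tested.

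On chromosome 10, 6 genes rose within 200000 bp, which are Ddt (18.0-fold, to 746 FPKM), Gstt3, Gstt1 (12.8-fold), Mif (2.75-fold), Mmp11 (0.381 to 13.6 FPKM) and Chchd10 (8.91-fold); Smarcb1 between them was at 67.6 and 95.1 FPKM without a call. Independent chance placement is argued against, since 1 of 1000 permutations of the calls put as many rising genes in any such window. When calls were permuted only within GC deciles, a test added after the result was seen, 21 did, and the highest window held 7. Permutations moved genes singly, whereas all rising genes here but Mmp11 and Chchd10 have a paralog in the cluster. They therefore do not weigh against neighbours that change together. Reads shared between paralogs are argued against as the whole source, because 2 rising genes, Mmp11 and Chchd10, have no paralog in the cluster. A single gain of copies is argued against by unequal folds, the largest being 14.4 times the smallest. Shared regulation of neighbours may apply and stays open as a hypothesis. Across the genome, adjacent pairs of rising genes numbered 64 against a mean of 34.2 and at most 56 in permutations within GC deciles. Those of falling genes numbered 37 against a mean of 16.0 and at most 30. These pairs can include neighbouring paralogs, such as Gstt3 and Gstt1 or Hspa1b and Hspa1a, and the permutations were not matched on expression. Since calls pair up across the genome, permutations that scatter them do not show that the chromosome 10 window is exceptional.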
